A study of Mus musculus with 191 samples.

How the data were processed

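Lung RNA of female mice was hybridised, per the labels, to Affymetrix mouse arrays with a biotin label by the standard Affymetrix protocol, after tissue storage in RNAlater, Trizol extraction and RNeasy purification. The deposited values are on a log scale, taken here as log2. Neither the base nor the normalization is stated, base 2 was not tested, and every fold rests on it. Values ran from -2.33 to 8.14 with a median of -0.386. Array means lay between -0.00269 and 0.00334 and array SDs between 1.01 and 1.44, so arrays were centred but not brought to 1 distribution. Control sets differed from each other by less than their spread gives, so the values look adjusted to match controls of different batches, which the labels do not state. Array files before this processing were not analysed here.

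Of 45101 probe sets 34958 had 1 gene symbol in the array's annotation, 932 several and 9211 none, and 34754 symbols were matched to current names. Each of 18194 genes was given by its probe set of the highest mean. Genes were tested where at least 3 arrays lay above the median of all values, which left 13524. Groups follow the labels, which do not say which control set was run beside which chemical, so each exposed group was set against every control set of its vehicle and array batch.

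A group-means model was fitted to all arrays together with limma 3.58.1 in R 4.3.3, so that the moderated spread is shared over groups. A gene was called where its Benjamini-Hochberg adjusted p was under 0.05, in the same direction, against every control set, and the log2 fold change is against the equal-weight mean of the sets. Analog pairs were contrasted in the same model. Concentration trends used the exposed arrays of a series and linear concentration, and are given as the fitted log2 change from the lowest to the highest concentration. The 30 gene lists were tested with camera at a preset inter-gene correlation of 0.01, two-sided, adjusted over 1020 tests, and again with an estimated correlation. "Adjusted over the list alone" is the Benjamini-Hochberg correction within a list. Tumour classes of the 26 chemicals were compared on log2 fold changes at the highest concentration, with array batch as covariate, and lists by 100000 permutations of the class within batches. Beta-actin 3' minus 5' values are from the array's control probe sets, with two-sided exact permutation tests.

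Named genes followed a rule: for each chemical at its highest concentration, each trend and the tumour class, among called genes the 8 largest rises and 8 largest falls, and up to 4 members of each list. Symbols of unnamed transcripts were passed over. Of these, genes whose call held with each array left out were preferred, a choice made after their calls were seen. The gene lists, groups, tests, naming rule and most alternatives were fixed before the data were examined. The alternatives were quantile normalization within the array batch, no filter, the mean of all probe sets, the arrays of a contrast alone, other uses of the control sets, log10 concentration, controls added at 0 ppm, the tumour class without covariate, an estimated list correlation and each array left out. Leaving out arrays of control comparisons, pairs, trends and lists, and the 2 arrays of an RNA integrity number under 7, was added after seeing the data, and 32 arrays have no such number. The code was tested on simulated data of 13524 genes, where it called 73% and 97% of 100 genes shifted by 0.5 and 1 in the NAPD layout of 3 against 3 arrays, with 11 false calls. A list of 20 genes shifted by 0.3 gave a camera adjusted p of 7.71e-61, with 0 of 1019 other tests called.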

Results

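RNA of the right lung lobe of female B6C3F1 mice, a hybrid strain used in rodent cancer bioassays, was measured on Affymetrix mouse expression arrays after 13 weeks of exposure. The series title concerns lung tumour prediction. The 133 arrays of exposed animals formed 34 groups for 26 chemicals given in chow, by gavage or by inhalation, and the 58 control arrays formed 14 sets. Methylene chloride and naphthalene were inhaled at 5 concentrations each, the others given at 1 dose. Groups held 3 to 5 arrays, which limits the precision, in 4 batches. Collection times are unlabelled, so changes of clock genes, and of other genes, may reflect time of day. Control sets carry the labels' codes, with ACO for air, CCO or CornOil for corn oil, FCO or RodentChow for rodent chow and WCO for distilled water. Each gene is given with its log2 fold change ± SE, where base 2 is assumed because the labels state none, against the equal-weight mean of the control sets of the same vehicle and batch. The adjusted p, from limma, is the largest over those sets, and a gene rose or fell where it was under 0.05 in the same direction against every set. For each gene said to have risen or fallen against controls, every exposed array lay on that side of the control mean unless a smaller number is given. Genes outside the naming rule, namely those of the pairs, of all but the highest concentrations of a series and of comparisons with 5 or fewer calls, were chosen after their values were seen.

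Control sets of the same vehicle and batch were compared as background. Between the corn oil sets CCO2 and CCO3 limma called 4 genes, among them Crhr1 (0.31 ± 0.07) and Galm (0.31 ± 0.07), higher in CCO2, and Hoxb5os (-0.31 ± 0.07), against 69 after quantile normalization and 0 with their own arrays alone. With the mean of all probe sets Crhr1 was at 0.12 (adjusted p = 0.936) and Galm at 0.12 (adjusted p = 0.527), and Galm was not called without the filter (adjusted p = 0.0522). The CCO2-CCO3 count was 0 without CCO2 replicate 1 or 4 or CCO3 replicate 1, 1 without CCO2 replicate 3 or CCO3 replicate 4 and 22 without CCO3 replicate 2. CCO5 against CCO6, ACO3 against ACO4, ACO3 against ACO5, and ACO4 against ACO5 gave 0 calls each by limma, with 394, 289, 282 and 384 genes at an unadjusted p under 0.05, and 7, 2, 0 and 2 calls after quantile normalization. The CCO5-CCO6 count was 1 without CCO5 replicate 1 or 3 or CCO6 replicate 3 or 4 and 2 without CCO5 replicate 4, the ACO3-ACO4 count 1 without ACO3 replicate 1 or 2 and 2 without ACO3 replicate 4, and the ACO3-ACO5 count 1 without ACO3 replicate 2 or 3 or ACO5 replicate 5 and 2 without ACO3 replicate 4. The median F statistic over probe sets was 0.619 between the 14 control sets, less than their arrays' spread would give by chance, and 4.16 between the 34 exposed groups. The control comparisons are therefore no independent background.

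Over 30 fixed gene lists and 34 exposure contrasts, camera called 236 of 1020 tests, 126 up and 110 down, with the preset correlation, and 8 with an estimated correlation, whose adjusted p is marked below as estimated. After quantile normalization 192 of the 236 were called in the same direction, among them 1 of 11 for skeletal muscle, 1 of 2 for neutrophils, 3 of 6 for mitochondrial respiration, 6 of 10 for alveolar type 2 cells, 3 of 5 for B and plasma cells, 3 of 5 for adipose tissue and 6 of 9 for cardiac muscle. By contrasts, the defence and metabolism lists were aryl hydrocarbon receptor (AhR) targets (9 up, 0 down), NRF2 and glutathione (15 up, 4 down), xenobiotic-metabolising enzymes of lung (8 up, 2 down), sterol and fatty acid synthesis (4 up, 1 down), PPAR targets and fatty acid oxidation (0 up, 0 down), mitochondrial respiration (1 up, 5 down), hypoxia (0 up, 0 down) and ER stress and ATF4 (4 up, 8 down). The lung cell lists were club cells (3 up, 10 down), goblet and mucous cells (6 up, 3 down), ciliated cells (12 up, 9 down), alveolar type 2 cells (4 up, 6 down), alveolar type 1 cells (2 up, 1 down), endothelium (3 up, 4 down) and smooth muscle and matrix (1 up, 4 down). The immune lists were macrophages (4 up, 2 down), neutrophils and acute inflammation (2 up, 0 down), T and NK cells (1 up, 9 down), B and plasma cells (3 up, 2 down), interferon response (4 up, 4 down) and antigen presentation (3 up, 3 down). Lists of other tissues were erythroid cells and blood (5 up, 4 down), cardiac muscle of pulmonary veins (2 up, 7 down), skeletal muscle (2 up, 9 down) and adipose tissue (1 up, 4 down). The remaining lists were cell cycle (11 up, 1 down), p53 targets and DNA damage (3 up, 0 down), circadian clock (8 up, 1 down), immediate early and handling stress (3 up, 2 down) and glucocorticoid response (2 up, 5 down).

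Dietary 1,5-naphthalenediamine (NAPD, 2000 ppm, n = 3) raised Cyp1a1, the monooxygenase induced through AhR, 21-fold over RodentChow (4.39 ± 0.28, adjusted p = 7.49e-30). With it, 4 of 7 measured AhR targets rose and 0 fell (4 and 0 adjusted over the list alone, median 1.19, camera adjusted p = 3.37e-30, or 3.78e-14 estimated), among them Cyp1b1 (1.19 ± 0.14). In the same lungs 21 of 29 NRF2 and glutathione genes rose and 0 fell (26 and 0 adjusted over the list alone, median 0.75, camera adjusted p = 1.8e-104, or 7.81e-08 estimated). They include the quinone reductase gene Nqo1 (1.90 ± 0.13), the glutathione peroxidase gene Gpx2 (2.18 ± 0.22), the carbonyl reductase gene Cbr3 (1.80 ± 0.19) and the cystine transporter gene Slc7a11 (0.58 ± 0.07). The carboxylesterase gene Ces1g rose 7.07-fold (2.82 ± 0.19, adjusted p = 3.57e-27). Plasma cell transcripts rose too, with the IgM heavy chain gene Ighm at 3.58 ± 0.78, adjusted p = 0.00155, Jchain at 3.06 ± 0.54 and Mzb1 at 1.35 ± 0.21. As a list, 4 of 15 B and plasma cell markers rose and 0 fell (5 and 0 adjusted over the list alone, median 0.17, camera adjusted p = 8.96e-07, or 0.489 estimated). The beta-actin 3' minus 5' value, a measure of RNA integrity, is lower in less degraded RNA. Its difference from controls was -0.30 (exact permutation p = 0.1, the smallest that 3 against 3 arrays allow). In all, 140 genes rose and 8 fell. For NAPD, 193 genes rose and 44 fell after quantile normalization.

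At the same dietary level, N-(1-naphthyl)ethylenediamine dihydrochloride (NEDD, n = 3), which also carries an amine on a naphthalene ring, raised Cyp1a1 3.84-fold (1.94 ± 0.28, adjusted p = 9.99e-07), and 12 genes rose and 0 fell in all. Compared directly, Cyp1a1 was higher with NAPD by 2.45 (95% interval 1.90 to 2.99, adjusted p = 2.01e-12), Nqo1 by 1.70 (95% interval 1.43 to 1.96, adjusted p = 1.47e-21), Ces1g by 2.61 (95% interval 2.24 to 2.99, adjusted p = 3.2e-24) and Ighm by 3.70 (95% interval 2.16 to 5.24, adjusted p = 0.000754). Marco, a macrophage scavenger receptor gene, was higher by 1.38 (95% interval 1.07 to 1.70, adjusted p = 6.03e-12). Between both, 4 of 7 AhR targets were higher and 0 lower with NAPD (4 and 0 adjusted over the list alone, median 1.19, camera adjusted p = 2.11e-20, or 1.43e-10 estimated). Also, 23 of 29 NRF2 and glutathione genes were higher and 0 lower (26 and 0 adjusted over the list alone, median 0.81, camera adjusted p = 6.25e-92, or 1.47e-07 estimated). In all, 194 genes were higher and 14 lower with NAPD. For NEDD, 2 genes rose and 0 fell after quantile normalization and its arrays alone gave 1 call. The NEDD count was 1 without NEDD replicate 3 or RodentChow replicate 1 or 2, 2 without NEDD replicate 1, 27 without RodentChow replicate 3 and 41 without NEDD replicate 2. For NAPD-NEDD, 251 genes were higher and 67 lower after quantile normalization and its arrays alone gave 542 calls. The NAPD-NEDD count was 135 without NAPD replicate 1.

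Pentachloronitrobenzene (PCNB, 8187 ppm in chow, n = 3) raised Cyp1a1 4.68-fold (2.23 ± 0.28, adjusted p = 3.5e-09), the 1 gene called. Of the AhR list, 1 of 7 genes rose and 0 fell (1 and 0 adjusted over the list alone, median 0.10, camera adjusted p = 3.01e-06, or 0.00576 estimated). The PCNB count was 2 without PCNB replicate 3 or RodentChow replicate 3. With 4-nitroanthranilic acid (NAAC, 10000 ppm in chow, n = 4), Cyp1a1 rose 2.59-fold (1.37 ± 0.24, adjusted p = 0.000706), a call kept with each array left out. The chromatin remodeller gene Smarcad1 (0.31 ± 0.06, adjusted p = 0.0189) was the other gene called, lost without FCO2 replicate 2 or 3 or NAAC replicate 1, 2 or 4 (0.29 to 0.31, adjusted p = 0.0768 to 0.427), after quantile normalization (adjusted p = 1) and with the mean of all probe sets (adjusted p = 0.369). Here 1 of 7 AhR targets rose and 0 fell (3 and 0 adjusted over the list alone, median 0.35, camera adjusted p = 0.0187, or 0.495 estimated), not called with its arrays alone (adjusted p = 0.324) or with the mean of all probe sets (median 0.16, adjusted p = 0.0666). Quantile normalization moved the median log2 fold change of all genes in NAAC from 0.10 to -0.01, and the beta-actin difference was -0.18 (exact permutation p = 0.0286). For NAAC, 1 gene rose and 0 fell after quantile normalization and its arrays alone gave 1911 calls. The NAAC count was 1 without FCO2 replicate 2 or 3 or NAAC replicate 1 or 4 and 4 without NAAC replicate 3.

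**Figure D1:**
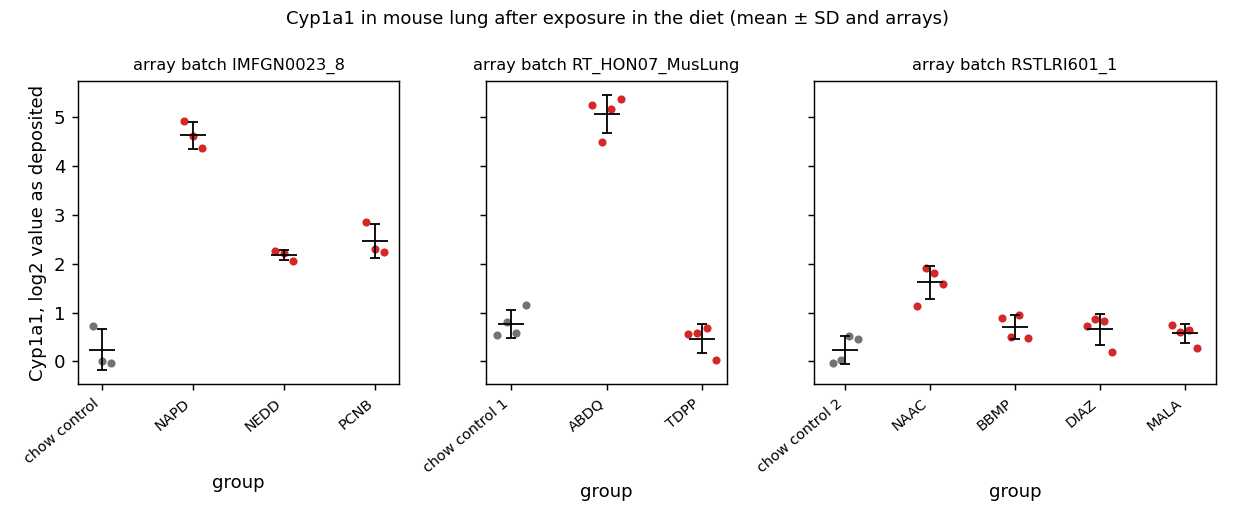
Cyp1a1 in lungs of mice on chow diets, as deposited log2 values, by array (points) with the group mean and SD (bars). Means were 4.63 with NAPD, 2.18 with NEDD, 2.46 with PCNB and 0.24 in RodentChow, 5.07 with ABDQ and 0.77 in FCO1, and 1.62 with NAAC and 0.24 in FCO2.

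1-Amino-2,4-dibromoanthraquinone (ABDQ, 20000 ppm in chow, n = 4) raised Cyp1a1 19.7-fold over FCO1 (4.30 ± 0.24, adjusted p = 8.87e-35) and Nqo1 2.14-fold (1.10 ± 0.12, adjusted p = 6.4e-13), calls that held with each array left out. With ABDQ, 3 of 7 AhR targets rose and 0 fell (4 and 0 adjusted over the list alone, median 0.46, camera adjusted p = 4.7e-11, or 1.24e-05 estimated). Further, 2 of 29 NRF2 and glutathione genes rose and 0 fell (12 and 0 adjusted over the list alone, median 0.32, camera adjusted p = 2.4e-13, or 0.489 estimated). Also, 2 of 26 cell cycle genes rose and 0 fell (10 and 0 adjusted over the list alone, median 0.21, camera adjusted p = 1.61e-07, or 0.739 estimated). The beta-actin difference was -0.19 (exact permutation p = 0.0286, the smallest that 4 against 4 arrays allow). In all, 87 genes rose and 37 fell. For ABDQ, 537 genes rose and 305 fell after quantile normalization and its arrays alone gave 2 calls. The ABDQ count was 12 without FCO1 replicate 4, 23 without ABDQ replicate 4, 66 without FCO1 replicate 3 and 460 without FCO1 replicate 2. With tris(2,3-dibromopropyl)phosphate (TDPP, 1000 ppm in chow, n = 4), 1 gene was called, the pregnancy-specific glycoprotein gene Psg23 (0.39 ± 0.08, adjusted p = 0.0247), lost without FCO1 replicate 1, 3 or 4 or TDPP replicate 1, 3 or 4 (0.32 to 0.40, adjusted p = 0.068 to 0.999). Among NRF2 and glutathione genes 0 of 29 rose and 0 fell (0 and 0 adjusted over the list alone, median 0.16, camera adjusted p = 2.2e-11, or 0.608 estimated). For TDPP, its arrays alone gave 0 calls. The TDPP count was 0 without FCO1 replicate 1, 3 or 4 or TDPP replicate 1, 3 or 4, 2 without TDPP replicate 2 and 11 without FCO1 replicate 2.

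Gavage of 2,3-benzofuran (BFUR, 240 mg/kg in corn oil, n = 3) raised Ces1g 3.89-fold (1.96 ± 0.19, adjusted p = 1.01e-14), Gpx2 2.95-fold (1.56 ± 0.22, adjusted p = 6.66e-08), the aldehyde dehydrogenase gene Aldh3a1 2.34-fold (1.23 ± 0.23, adjusted p = 0.000332) and Nqo1 2.22-fold (1.15 ± 0.13, adjusted p = 9.93e-11). These 4 calls held with each array left out. With BFUR, 16 of 29 NRF2 and glutathione genes rose and 0 fell (23 and 0 adjusted over the list alone, median 0.51, camera adjusted p = 9.79e-29, or 0.0543 estimated). In addition, 6 of 16 ciliated cell markers rose and 0 fell (13 and 0 adjusted over the list alone, median 0.47, camera adjusted p = 4.01e-10, or 0.461 estimated). In all, 224 genes rose and 27 fell. For BFUR, 254 genes rose and 74 fell after quantile normalization and its arrays alone gave 1 call, without Gpx2, Aldh3a1 or Nqo1 (adjusted p = 0.0593 to 0.363). The BFUR count was 18 without BFUR replicate 1, 69 without CornOil replicate 2, 136 without CornOil replicate 1, 425 without BFUR replicate 3 and 1008 without BFUR replicate 2.

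Coumarin (COUM, 200 mg/kg by gavage in corn oil, n = 4) raised Ces1g 4.69-fold (2.23 ± 0.14, adjusted p = 3.75e-23), Nqo1 2.37-fold (1.24 ± 0.10, adjusted p = 2.34e-16), Cbr3 (1.20 ± 0.15), Gpx2 (1.14 ± 0.16) and the amine oxidase gene Aoc1 (1.09 ± 0.15). Agr2, for a disulfide isomerase of mucus-secreting cells, rose 2.04-fold (1.03 ± 0.15, adjusted p = 2.74e-05). The fibrillar collagen genes Col3a1 (-0.87 ± 0.15, adjusted p = 0.0003) and Col1a1 (-0.80 ± 0.15) fell. These 8 calls held with each array left out. Under coumarin, 7 of 29 NRF2 and glutathione genes rose and 0 fell (7 and 0 adjusted over the list alone, median 0.20, camera adjusted p = 8.27e-10, or 0.747 estimated). Of the matrix list, 0 of 22 smooth muscle and matrix genes rose and 8 fell (0 and 12 adjusted over the list alone, median -0.43, camera adjusted p = 1.29e-08, or 0.489 estimated). Also, 0 of 14 endothelial markers rose and 3 fell (0 and 7 adjusted over the list alone, median -0.38, camera adjusted p = 0.00134, or 0.999 estimated). In all, 549 genes rose and 220 fell. For COUM, 1231 genes rose and 319 fell after quantile normalization and its arrays alone gave 17 calls, without Cbr3, Col3a1 or Col1a1 (adjusted p = 0.0922 to 0.441). The COUM count was 145 without COUM replicate 3, 149 without COUM replicate 4, 205 without CCO3 replicate 2, 369 without CCO2 replicate 3, 1644 without COUM replicate 1 and 1749 without COUM replicate 2.

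With 1,2-dibromoethane (DBET, 62 mg/kg by gavage in corn oil, n = 4), the mucosal chemokine gene Cxcl17 rose 2.86-fold (1.52 ± 0.19, adjusted p = 2.13e-07), together with Gpx2 (0.97 ± 0.16) and Ces1g (0.96 ± 0.14). Of club cells, the secretory cells of the small airways, 7 of 18 markers rose and 0 fell (11 and 0 adjusted over the list alone, median 0.56, camera adjusted p = 9.74e-13, or 0.166 estimated). Examples were the receptor subunit gene Gabrp (1.10 ± 0.16, adjusted p = 1.41e-05) and the retinal dehydrogenase genes Aldh1a7 (0.78 ± 0.15) and Aldh1a1 (0.73 ± 0.10). Of ciliated cells, 7 of 16 markers rose and 0 fell (9 and 0 adjusted over the list alone, median 0.49, camera adjusted p = 1.52e-10, or 0.426 estimated), with the dynein light chain gene Dynlrb2 at 0.77 ± 0.15 and the radial spoke gene Rsph1 at 0.67 ± 0.12. Together with these, 11 of 29 NRF2 and glutathione genes rose and 0 fell (13 and 0 adjusted over the list alone, median 0.32, camera adjusted p = 9.74e-13, or 0.494 estimated). The calls of the 8 named genes held with each array left out. In all, 312 genes rose and 49 fell. For DBET, 161 genes rose and 100 fell after quantile normalization and its arrays alone gave 25 calls, without Aldh1a1 or Dynlrb2 (adjusted p = 0.0551 to 0.0804). The DBET count was 150 without CCO3 replicate 4, 174 without DBET replicate 4, 204 without DBET replicate 2, 207 without CCO2 replicate 2, 210 without DBET replicate 1, 214 without CCO2 replicate 1, 216 without CCO3 replicate 1 and 218 without CCO2 replicate 4.

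Benzene (BENZ, 100 mg/kg by gavage in corn oil, n = 4) gave 4 calls, all rises. Dglucy, for a D-glutamate cyclase, rose 1.42-fold (0.51 ± 0.05, adjusted p = 1.58e-10), which held with each array left out. The epoxide hydrolase gene Ephx1 (0.81 ± 0.13, adjusted p = 0.0109) lost its call without BENZ replicate 1, 2 or 3 or CCO2 replicate 1 (0.77 to 0.82, adjusted p = 0.0534 to 0.509), the p53 target Phlda3 (0.70 ± 0.13, adjusted p = 0.0283) without BENZ replicate 1, 2 or 3, CCO2 replicate 1, 2 or 3 or CCO3 replicate 3 or 4 (0.62 to 0.71, adjusted p = 0.0543 to 0.509), and the carboxylesterase gene Ces2e (0.33 ± 0.06, adjusted p = 0.0467) without BENZ replicate 1, 2, 3 or 4 or CCO2 replicate 1, 2, 3 or 4 (0.31 to 0.35, adjusted p = 0.0643 to 0.509). For BENZ, its arrays alone gave 0 calls. The BENZ count was 1 without BENZ replicate 1, 2 or 3 or CCO2 replicate 1 and 2 without CCO2 replicate 2.

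Gavage of 1,4-dichlorobenzene (DCBZ, 600 mg/kg in corn oil, n = 4) raised Ces1g 3.53-fold (1.82 ± 0.14, adjusted p = 3.35e-18), Nqo1 2.03-fold (1.02 ± 0.10, adjusted p = 2.72e-12), Gpx2 (1.02 ± 0.16) and Cbr3 (0.75 ± 0.14), and the nuclear noncoding RNA Malat1 fell 2.28-fold (-1.19 ± 0.19, adjusted p = 0.000183). Each of these calls held with every array left out. Malat1 was at -0.55 (adjusted p = 0.138) with the mean of all its probe sets. With DCBZ, 11 of 29 NRF2 and glutathione genes rose and 0 fell (15 and 0 adjusted over the list alone, median 0.28, camera adjusted p = 3.06e-21, or 0.173 estimated). Further, 0 of 16 ciliated cell markers rose and 0 fell (10 and 0 adjusted over the list alone, median 0.31, camera adjusted p = 2.65e-09, or 0.489 estimated). In all, 142 genes rose and 51 fell. For DCBZ, 193 genes rose and 248 fell after quantile normalization and its arrays alone gave 5 calls, without Gpx2, Cbr3 or Malat1 (adjusted p = 0.128 to 0.319). The DCBZ count was 114 without DCBZ replicate 3.

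With 1,2,3-trichloropropane (TCPN, 60 mg/kg by gavage in corn oil, n = 4), Ces1g rose 2.55-fold (1.35 ± 0.14, adjusted p = 6.24e-11), the glutathione transferase gene Gsto1 2.06-fold (1.04 ± 0.14, adjusted p = 4.53e-06) and Cxcl17 2.27-fold (1.18 ± 0.18, adjusted p = 0.000324). The inducible prostaglandin synthase gene Ptgs2 (1.31 ± 0.18, adjusted p = 1.78e-05) and the p53 target Ccng1 (1.11 ± 0.17, adjusted p = 0.000233) rose too, and these 5 calls held with each array left out and after quantile normalization. The acute-phase gene Saa1 was at 1.04 ± 0.22, adjusted p = 0.00736, with 2 of 4 arrays above the control mean, and at -0.08 (adjusted p = 0.812) without TCPN replicate 2. As a list, 7 of 26 cell cycle genes rose and 0 fell (10 and 0 adjusted over the list alone, median 0.22, camera adjusted p = 0.000785, or 0.999 estimated). In all, 1045 genes rose and 222 fell, or 84 and 122 after quantile normalization. Its arrays alone gave 14 calls, without Ccng1 or Saa1 (adjusted p = 0.051 to 0.429). The TCPN count was 512, 610, 740 and 759 without TCPN replicates 1 to 4 in turn. It was 748 without CCO5 replicate 5, and 683, 132 and 1999 without CCO6 replicates 1, 4 and 5 in turn. Values within TCPN arrays had a mean SD of 1.36 against 1.23 in controls, and quantile normalization moved the median log2 fold change of all genes from 0.07 to -0.05.

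Malathion in chow (MALA, n = 4, with the dose given as 14800 ppm in one label and 16000 in another) lowered the heat shock chaperone gene Hsph1 4.11-fold (-2.04 ± 0.33, adjusted p = 1.08e-05) and raised Cirbp, for a cold-inducible RNA-binding protein, 2.98-fold (1.58 ± 0.24, adjusted p = 2e-06). Pon1, whose product hydrolyses organophosphate oxons, fell 2.11-fold (-1.08 ± 0.21, adjusted p = 0.000455), as did the club cell secretoglobin gene Scgb3a2 (-0.71 ± 0.12, adjusted p = 6.29e-05). Lrg1, for a secreted leucine-rich glycoprotein, rose (1.22 ± 0.23, adjusted p = 0.000199), and so did the aldo-keto reductase gene Akr1b8 (1.21 ± 0.18) and Gpx2 (1.02 ± 0.19), each above the control mean in 3 of 4 arrays. The clock activator gene Arntl fell (-0.79 ± 0.18, adjusted p = 0.00613). These 8 calls held with each array left out. With malathion 0 of 18 club cell markers rose and 2 fell (0 and 4 adjusted over the list alone, median -0.28, camera adjusted p = 4.32e-06, or 0.739 estimated) and 6 of 29 NRF2 and glutathione genes rose and 1 fell (7 and 1 adjusted over the list alone, median 0.15, camera adjusted p = 0.00018, or 0.999 estimated). In addition, 3 of 18 circadian clock genes rose and 1 fell (10 and 3 adjusted over the list alone, median 0.33, camera adjusted p = 0.00703, or 0.489 estimated). In all, 134 genes rose and 97 fell. For MALA, 383 genes rose and 312 fell after quantile normalization and its arrays alone gave 355 calls, without Scgb3a2, Akr1b8 or Gpx2 (adjusted p = 0.0799 to 0.12). The MALA count was 55 without MALA replicate 3, 92 without FCO2 replicate 2, 103 without MALA replicate 1, 130 without FCO2 replicate 3 and 151 without FCO2 replicate 4.

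Diazinon (DIAZ, 200 ppm in chow, n = 4), like malathion an organophosphorus insecticide, gave 0 calls by limma, with 1524 genes at an unadjusted p under 0.05 and 0 calls after quantile normalization. As a list, 0 of 9 antigen presentation genes rose and 0 fell (6 and 0 adjusted over the list alone, median 0.38, camera adjusted p = 1.07e-05, or 0.729 estimated). The DIAZ count was 1 without DIAZ replicate 1 or FCO2 replicate 2 or 3 and 2 without DIAZ replicate 3. The dietary levels of both insecticides differed. Compared directly, Akr1b8 was higher with malathion by 1.04 (95% interval 0.68 to 1.40, adjusted p = 8.87e-05), in 3 of 4 arrays, while Scgb3a2 was lower, at -0.90 (95% interval -1.14 to -0.65, adjusted p = 1.03e-07), and so was Cyp2f2, the main club cell monooxygenase gene, at -0.47 (95% interval -0.67 to -0.27, adjusted p = 0.00475). Between both, 2 of 18 clock genes were higher and 0 lower with malathion (2 and 1 adjusted over the list alone, median 0.26, camera adjusted p = 5.34e-06, or 0.0092 estimated). In all, 40 genes were higher and 92 lower with malathion. For MALA-DIAZ, 89 genes were higher and 67 lower after quantile normalization and its arrays alone gave 1 call, without Akr1b8, Scgb3a2 or Cyp2f2 (adjusted p = 0.0516 to 0.164). The MALA-DIAZ count was 20 without MALA replicate 3, 32 without MALA replicate 1, 39 without DIAZ replicate 3, 84 without DIAZ replicate 4 and 202 without MALA replicate 4.

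Dietary 2,2-bis(bromomethyl)-1,3-propanediol (BBMP, 1250 ppm, n = 4) raised Cirbp 2.64-fold over FCO2 (1.40 ± 0.24, adjusted p = 7.62e-05) and Akr1b8 2.12-fold (1.09 ± 0.18, adjusted p = 5.57e-05), and both calls held with each array left out and after quantile normalization. Lrg1 was at 1.07 ± 0.23, adjusted p = 0.00296 and Gpx2 at 0.87 ± 0.19, adjusted p = 0.00362, with adjusted p = 0.0922 and 0.126 without BBMP replicate 3, and Gpx2 was not called after quantile normalization (adjusted p = 0.0763). With BBMP, 10 of 29 NRF2 and glutathione genes rose and 1 fell (13 and 1 adjusted over the list alone, median 0.25, camera adjusted p = 0.0095, or 0.999 estimated), not called without BBMP replicate 1 or 3 (adjusted p = 0.0523 to 0.071). In all, 1411 genes rose and 54 fell, or 27 and 3 after quantile normalization. The BBMP count was 3084, 8 and 102 without BBMP replicates 2 to 4 in turn. It was 55, 391 and 644 without FCO2 replicates 2 to 4 in turn. Values within BBMP arrays had a mean SD of 1.33 against 1.23 in FCO2, and the beta-actin difference was -0.20 (exact permutation p = 0.0286).

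N-methylolacrylamide (MACR, 50 mg/kg by gavage in water, n = 4) raised the matrix genes Postn (1.40 ± 0.32, adjusted p = 0.0312) and Ogn (1.25 ± 0.36) and the mitochondrially encoded respiratory subunit gene ND5 (1.15 ± 0.33). All 3 calls held after quantile normalization and were lost without MACR replicate 1 or 3 or WCO1 replicate 1, 3 or 4 (adjusted p = 0.0531 to 0.235). With it, 0 of 15 glucocorticoid response genes rose and 3 fell (0 and 9 adjusted over the list alone, median -0.60, camera adjusted p = 0.000529, or 0.939 estimated), not called without WCO1 replicate 2 (adjusted p = 0.0561). In all, 567 genes rose and 141 fell, and 82.4% of the squared log2 fold changes lay along the first 2 axes of variation within control sets. For MACR, 1491 genes rose and 1927 fell after quantile normalization and its arrays alone gave 0 calls. The MACR count was 0 without MACR replicate 1 or 3 or WCO1 replicate 4, 7 without WCO1 replicate 1, 26 without WCO1 replicate 3, 1135 without MACR replicate 4 and 2695 without WCO1 replicate 2. By the same route, 2-chloromethylpyridine hydrochloride (CMPH, 250 mg/kg, n = 4) gave 0 calls by limma, with 965 genes at an unadjusted p under 0.05, and the cell cycle inhibitor gene Cdkn1a was at -0.99 ± 0.25, adjusted p = 0.354. For glucocorticoid response genes, 0 of 15 rose and 0 fell (0 and 8 adjusted over the list alone, median -0.52, camera adjusted p = 1.24e-08, or 0.34 estimated). For CMPH, 0 genes rose and 1 fell after quantile normalization. The CMPH count was 1 without WCO1 replicate 1.

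Iodoform (IODO, 93 mg/kg by gavage in corn oil, n = 4) raised the endothelial genes Tie1, for a receptor kinase (0.69 ± 0.17, adjusted p = 0.00634), and Egfl7 (0.62 ± 0.14). Akr1c14, for an aldo-keto reductase (-1.29 ± 0.28, adjusted p = 0.00426), Postn (-1.13 ± 0.32) and ND5 (-1.07 ± 0.33), top genes of the control axes, fell. These 5 calls were lost without CCO4 replicate 1 or 3 or IODO replicate 2 (adjusted p = 0.0521 to 0.293). In all, 2105 genes rose and 1603 fell, and 77.8% of the squared log2 fold changes lay along the same axes. The beta-actin difference was -0.34 (exact permutation p = 0.0286). For IODO, its arrays alone gave 0 calls. The IODO count was 2 without IODO replicate 2, 7 without CCO4 replicate 1 and 9 without CCO4 replicate 3.

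Trichlorofluoromethane (TCFM, 3925 mg/kg by gavage in corn oil, n = 4) raised the clock genes Dbp (1.85 ± 0.42, adjusted p = 0.0308) and Per2 (0.53 ± 0.13, adjusted p = 0.0395) and lowered Arntl (-0.73 ± 0.18, adjusted p = 0.04) and the endoplasmic reticulum chaperone gene Hspa5 (-0.77 ± 0.20, adjusted p = 0.0494). These 4 calls were lost without CCO4 replicate 1 or 3 or TCFM replicate 1, 2 or 3 (adjusted p = 0.0514 to 0.339). With the mean of all probe sets Per2 was at 0.38 (adjusted p = 0.0734) and Hspa5 at -0.58 (adjusted p = 0.059), and Hspa5 was not called without the filter (adjusted p = 0.0602). Of the clock list, 2 of 18 genes rose and 2 fell (6 and 4 adjusted over the list alone, median 0.18, camera adjusted p = 0.0241, or 0.735 estimated), with a camera adjusted p of 0.125 after quantile normalization and 0.194 without the filter, and not called without CCO4 replicate 2 or 4 (adjusted p = 0.0765 to 0.0768). In all, 26 genes rose and 40 fell. For TCFM, 1027 genes rose and 513 fell after quantile normalization and its arrays alone gave 137 calls, without Dbp, Per2, Arntl or Hspa5 (adjusted p = 0.0616 to 0.0876). The TCFM count was 4 without CCO4 replicate 1 or TCFM replicate 3, 5 without CCO4 replicate 3 or TCFM replicate 1, 12 without TCFM replicate 2, 906 without CCO4 replicate 4, 1119 without TCFM replicate 4 and 1250 without CCO4 replicate 2. Iodoform and trichlorofluoromethane, both halogenated methanes, were given at different doses. Compared directly, Per2 was lower with iodoform, at -0.62 (95% interval -0.87 to -0.37, adjusted p = 0.0046), which held with each array left out. Between both, 1 of 18 clock genes were higher and 2 lower with iodoform (3 and 7 adjusted over the list alone, median -0.17, camera adjusted p = 7.37e-05, or 0.0319 estimated). In all, 232 genes were higher and 20 lower with iodoform. For IODO-TCFM, 53 genes were higher and 57 lower after quantile normalization and its arrays alone gave 0 calls. The IODO-TCFM count was 4 without IODO replicate 2, 13 without TCFM replicate 1, 17 without TCFM replicate 4, 98 without IODO replicate 1, 839 without TCFM replicate 2, 955 without IODO replicate 4 and 2120 without IODO replicate 3.

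Inhaled tetrafluoroethylene (TFEL, 1250 ppm, n = 4) raised the transcription factor gene Nfix 2.50-fold (1.32 ± 0.20, adjusted p = 1.48e-06), Rsrp1, for an arginine- and serine-rich protein (1.29 ± 0.27, adjusted p = 0.000681), and the endothelial gene Plvap (0.79 ± 0.20, adjusted p = 0.00516), and lowered Malat1 2.24-fold (-1.17 ± 0.23, adjusted p = 0.000359). These 4 calls held with each array left out. Malat1 was at -0.40 (adjusted p = 0.183) with the mean of all its probe sets. Of the vessel lining, 2 of 14 endothelial markers rose and 0 fell (3 and 0 adjusted over the list alone, median 0.19, camera adjusted p = 0.0306, or 0.999 estimated), not called without ACO1 replicate 3 or TFEL replicate 4 (adjusted p = 0.0608 to 0.084). In all, 764 genes rose and 200 fell, or 659 and 989 after quantile normalization. The beta-actin difference was -0.38 (exact permutation p = 0.0286) and the mean RNA integrity number 9.07 against 7.93 in ACO1. RNA integrity thus cannot be told apart from exposure for these calls. The TFEL count was 307 and 572 without ACO1 replicates 3 and 4 in turn and 391 and 448 without TFEL replicates 2 and 3.

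With inhaled tetrafluororethane, the labels' spelling, read here as tetrafluoroethane (TFEA, 50000 ppm, n = 4), the endothelial transcription factor gene Sox18 (0.88 ± 0.20, adjusted p = 0.0301) rose and the mitochondrial ribosomal gene Mrpl33 (-0.41 ± 0.09, adjusted p = 0.0301) fell, and both calls were lost without ACO1 replicate 2, 3 or 4 or TFEA replicate 1 or 2 (adjusted p = 0.0513 to 0.999). Mrpl33 was at -0.17 (adjusted p = 0.101) with the mean of all probe sets. In all, 8 genes rose and 5 fell, or 247 and 376 after quantile normalization, and its arrays alone gave 0 calls. The TFEA count was 23, 3, 0 and 4 without ACO1 replicates 1 to 4 in turn. It was 0, 0, 142 and 825 without TFEA replicates 1 to 4. The fluorinated alkene and alkane were given at different concentrations. Compared directly, limma called 0 genes, with 849 at an unadjusted p under 0.05, 0 calls after quantile normalization and a median half-width of 0.204 for the 95% intervals. TFEL minus TFEA was 0.53 (95% interval 0.14 to 0.92, adjusted p = 0.628) for Nfix, -0.51 (95% interval -0.96 to -0.06, adjusted p = 0.729) for Malat1 and 0.06 (95% interval -0.33 to 0.45, adjusted p = 0.993) for Sox18. The TFEL-TFEA count was 258 without TFEA replicate 1.

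Inhaled vanadium pentoxide (VANP, 2 mg/m3, n = 4) raised the macrophage elastase gene Mmp12 4.57-fold (2.19 ± 0.12, adjusted p = 1.56e-27) and the cathepsin gene Ctsk 4.46-fold (2.16 ± 0.10, adjusted p = 8.76e-33). Of macrophages, 14 of 27 markers rose and 0 fell (19 and 0 adjusted over the list alone, median 0.44, camera adjusted p = 3.37e-30, or 3.05e-05 estimated). They include the chemokine gene Ccl6 (1.30 ± 0.14) and the collagenase gene Mmp8 (1.07 ± 0.15). The acidic chitinase gene Chia1 (1.81 ± 0.18, adjusted p = 2.58e-10) and Lcn2, for an iron-chelating acute-phase protein (1.03 ± 0.15, adjusted p = 5.47e-05), rose too. Of alveolar type 2 cells, which make surfactant, 10 of 16 markers rose and 0 fell (13 and 0 adjusted over the list alone, median 0.52, camera adjusted p = 1.05e-18, or 0.109 estimated), with the aspartic protease gene Napsa at 0.97 ± 0.12 and Etv5 at 0.85 ± 0.16. In this group 5 of 9 antigen presentation genes rose and 0 fell (5 and 0 adjusted over the list alone, median 0.46, camera adjusted p = 2.78e-08, or 0.426 estimated), with the class II chaperone gene Cd74 at 0.79 ± 0.10 and H2-Aa at 0.58 ± 0.11. Igfbp6, for a growth factor binding protein (-1.35 ± 0.14, adjusted p = 5.79e-09), and the proteoglycan gene Spock2 (-0.99 ± 0.15) fell. The 12 calls named held with each array left out. Lower as lists, 0 of 14 endothelial markers rose and 2 fell (0 and 5 adjusted over the list alone, median -0.44, camera adjusted p = 1.78e-06, or 0.747 estimated). Also, 0 of 9 adipose tissue genes rose and 2 fell (0 and 4 adjusted over the list alone, median -0.79, camera adjusted p = 0.00012, or 0.898 estimated). Without ACO3 replicate 4 the median was -0.56 (camera adjusted p = 0.00228) and 0 of these genes were called. In all, 409 genes rose and 177 fell. For VANP, 592 genes rose and 361 fell after quantile normalization.

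Naphthalene was inhaled at 0.5, 3, 10, 20 and 30 ppm (NPTH, n = 4 each) and compared with the air sets ACO3, ACO4 and ACO5. At 30 ppm Lrg1 rose 4.37-fold (2.13 ± 0.18, adjusted p = 3.35e-14), the lipid transporter gene Mfsd2a 3.21-fold (1.68 ± 0.11, adjusted p = 3.06e-22) and Lcn2 3.10-fold (1.63 ± 0.15, adjusted p = 2.11e-11), while Pon1 fell 4.31-fold (-2.11 ± 0.17, adjusted p = 1.58e-15). Of mucus-producing cells, 3 of 9 goblet and mucous markers rose and 0 fell (6 and 0 adjusted over the list alone, median 0.38, camera adjusted p = 1.14e-11, or 0.0368 estimated), with Agr2 at 1.91 ± 0.14 and the anion exchanger gene Slc26a4 at 1.07 ± 0.13. Of club cells, 0 of 18 markers rose and 5 fell (1 and 7 adjusted over the list alone, median -0.19, camera adjusted p = 0.00165, or 0.999 estimated), with Gabrp at -1.12 ± 0.14 and the claudin gene Cldn10 at -0.80 ± 0.13. Of alveolar type 2 cells, 2 of 16 markers rose and 0 fell (6 and 0 adjusted over the list alone, median 0.32, camera adjusted p = 1.65e-11, or 0.426 estimated), with the alarmin gene Il33 at 1.58 ± 0.20. At this concentration 6 of 29 NRF2 and glutathione genes rose and 1 fell (11 and 2 adjusted over the list alone, median 0.16, camera adjusted p = 3.82e-09, or 0.784 estimated), with Nqo1 at 1.15 ± 0.09, Gpx2 at 1.12 ± 0.15 and Cbr3 at 1.12 ± 0.13. Likewise 9 of 21 sterol and fatty acid synthesis genes rose and 0 fell (11 and 0 adjusted over the list alone, median 0.34, camera adjusted p = 3.83e-16, or 0.109 estimated), with the farnesyl diphosphate synthase gene Fdps at 0.82 ± 0.12 and the desaturase gene Scd1 at 0.82 ± 0.12. The 14 calls named held with each array left out. In all, 214 genes rose and 63 fell, or 409 and 95 after quantile normalization.

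At lower naphthalene concentrations, Agr2 rose at 3 ppm (1.06 ± 0.14, adjusted p = 2.42e-05), 10 ppm (1.78 ± 0.14) and 20 ppm (1.52 ± 0.14), and Nqo1 at 10 ppm (1.11 ± 0.09, adjusted p = 3.19e-13) and 20 ppm (1.08 ± 0.09). At 20 ppm Lrg1 rose (1.80 ± 0.18, adjusted p = 1.84e-10) and Pon1 fell (-1.52 ± 0.17, adjusted p = 7.7e-09). At 0.5 and 3 ppm the RNA-binding protein gene Hnrnpab (-1.25 ± 0.15, adjusted p = 2.25e-06, and -1.40 ± 0.15) and the splicing gene Srrm2 (-1.11 ± 0.15, adjusted p = 0.000173, and -1.12 ± 0.15) fell. Each of these calls held with every array left out. With the mean of all probe sets, Hnrnpab was at -0.10 (adjusted p = 0.774) and -0.19 (adjusted p = 0.756) and Srrm2 at -0.20 (adjusted p = 0.729) and -0.35 (adjusted p = 0.545). At 10 ppm 2 of 16 ciliated cell markers rose and 0 fell (6 and 0 adjusted over the list alone, median 0.33, camera adjusted p = 3.83e-16, or 0.121 estimated). At 20 ppm 0 of 18 club cell markers rose and 6 fell (0 and 7 adjusted over the list alone, median -0.33, camera adjusted p = 0.000104, or 0.93 estimated). Further, 5 of 18 clock genes rose and 2 fell (8 and 3 adjusted over the list alone, median 0.20, camera adjusted p = 0.000188, or 0.121 estimated). Genes that rose and fell numbered 17 and 33 at 0.5 ppm, 10 and 38 at 3 ppm, 57 and 18 at 10 ppm, and 151 and 135 at 20 ppm. After quantile normalization they numbered 23 and 69, 22 and 69, 112 and 36, and 270 and 202. The arrays of 0.5 ppm alone gave 17 calls. The NPTH 0.5 ppm count was 21 without exposed replicate 2, 30 without exposed replicate 3, 31 without ACO5 replicate 5 and 32 without ACO5 replicate 2 or exposed replicate 1. The NPTH 3 ppm count was 28 without exposed replicate 1 and 30 without ACO3 replicate 1 or exposed replicate 3. The NPTH 10 ppm count was 38 without exposed replicate 2 and 48 without exposed replicate 4. The NPTH 20 ppm count was 158 without exposed replicate 3 and 184 without exposed replicate 2.

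Across the exposed naphthalene groups, the change fitted from 0.5 to 30 ppm was -2.47 ± 0.12 for Pon1 (adjusted p = 3.13e-12), 2.14 ± 0.13 for Lrg1 (adjusted p = 9.8e-11) and 1.59 ± 0.12 for Il33 (adjusted p = 4.31e-09). The endothelial gene Kdr (-0.71 ± 0.09) and plasma protein genes Alb (-1.46 ± 0.37) and Ttr (-1.36 ± 0.39) fell with concentration. Alb and Ttr, top genes of control axis 2, were not called with ACO4 or ACO5 at 0 ppm (adjusted p = 0.0639 to 0.316). Hnrnpab rose with concentration (1.67 ± 0.21, or 0.07 (adjusted p = 0.151) with the mean of all probe sets). Its means were 2.62, 2.47 and 4.09 at 0.5, 3 and 30 ppm against 3.83 to 3.91 in controls. In all, 1228 genes rose and 4291 fell with concentration, or 2047 and 2569 after quantile normalization.

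**Figure D2:**
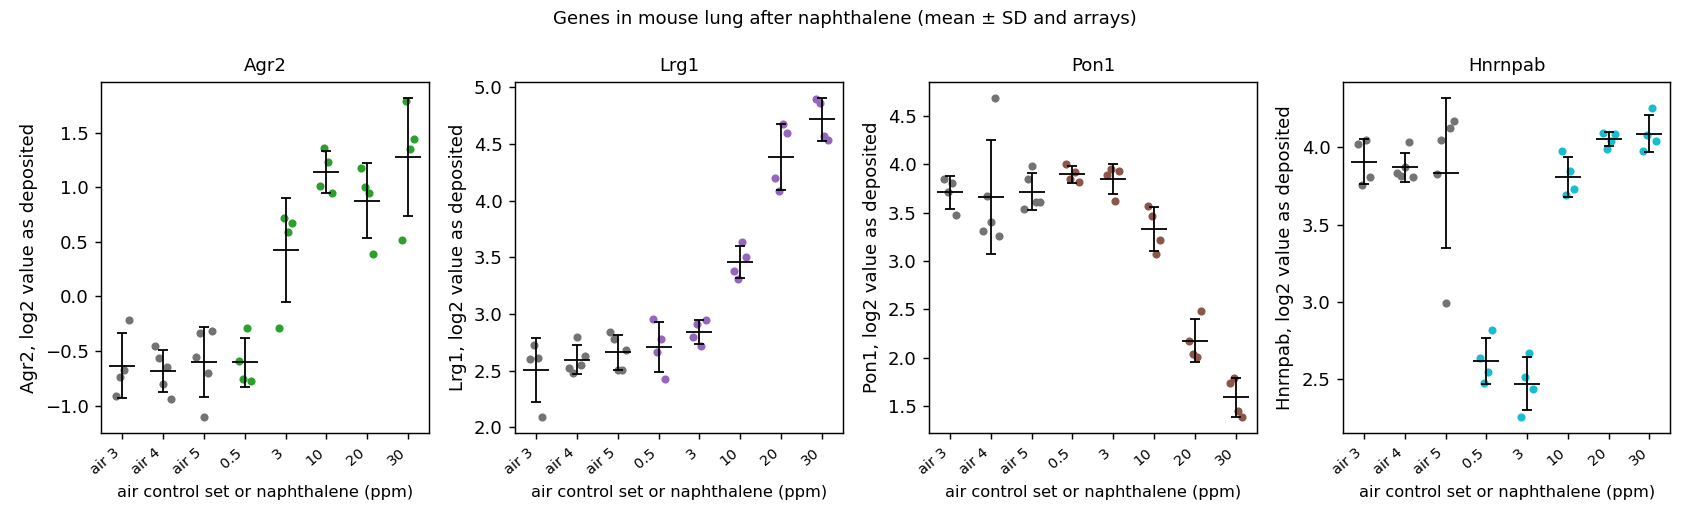
Log2 values as deposited of Lrg1, Agr2, Pon1 and Hnrnpab by naphthalene concentration in ppm and in the air control sets, by array (points) with the group mean and SD (bars). Mean Lrg1 was 2.71 at 0.5 ppm and 4.72 at 30 ppm and mean Agr2 -0.61 and 1.27.

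Methylene chloride was inhaled at 100, 500, 2000, 3000 and 4000 ppm (MECL, n = 4, or 5 at 100 ppm) and compared with the same air sets. At 4000 ppm the clock output gene Dbp rose 12.3-fold (3.62 ± 0.34, adjusted p = 7.97e-10). With it, 10 of 18 circadian clock genes rose and 3 fell (12 and 4 adjusted over the list alone, median 0.73, camera adjusted p = 3.04e-22, or 1.78e-09 estimated). The repressor genes Nr1d2 (1.97 ± 0.29) and Nr1d1 (1.47 ± 0.22), the period genes Per3 (1.46 ± 0.14) and Per2 (1.21 ± 0.10) and the transcription factor genes Tef (1.20 ± 0.13) and Hlf (1.00 ± 0.10) rose, while the activator genes Arntl (-1.58 ± 0.15, adjusted p = 1.52e-11) and Npas2 (-0.89 ± 0.12) fell. The matrix genes Spon2 (-1.37 ± 0.15, adjusted p = 1.18e-07) and Eln (-1.19 ± 0.16) and the binding protein gene Igfbp3 (-0.96 ± 0.12) fell, and the tetraspanin gene Tspan4 rose (1.44 ± 0.13, adjusted p = 1.35e-10). These 13 calls held with each array left out. At 3000 ppm Dbp (2.88 ± 0.34, adjusted p = 8.02e-06) rose and Arntl (-1.36 ± 0.15, adjusted p = 1.98e-08) fell. In addition, 9 of 18 clock genes rose and 3 fell (11 and 4 adjusted over the list alone, median 0.53, camera adjusted p = 4.83e-10, or 0.00022 estimated). Genes that rose and fell numbered 37 and 41 at 3000 ppm and 34 and 34 at 4000 ppm. For MECL 3000 ppm, 80 genes rose and 224 fell after quantile normalization and its arrays alone gave 39 calls. The MECL 3000 ppm count was 38 without exposed replicate 1, 40 without exposed replicate 2 and 47 without ACO3 replicate 3. For MECL 4000 ppm, 44 genes rose and 59 fell after quantile normalization. The MECL 4000 ppm count was 42 without exposed replicate 2.

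At lower methylene chloride concentrations, 2000 ppm raised Wfdc3, for a whey acidic protein domain (0.33 ± 0.05, adjusted p = 0.00104), and lowered the matrix gene Smoc2 (-0.31 ± 0.05, adjusted p = 0.0234), the 2 genes called. Wfdc3 held with each array left out but was at 0.18 (adjusted p = 0.052) with the mean of all its probe sets. Smoc2 lost its call without ACO3 replicate 2 or 4, ACO4 replicate 3 or 4 or MECL 2000 ppm replicate 2 or 3 (-0.25 to -0.30, adjusted p = 0.0539 to 0.218). At 500 ppm limma called 0 genes, with 1620 at an unadjusted p under 0.05, and at 100 ppm 2 rose and 18 fell. For MECL 100 ppm, 217 genes rose and 543 fell after quantile normalization and its arrays alone gave 146 calls. The MECL 100 ppm count was 0 without exposed replicate 2 or 5, 1 without ACO3 replicate 3, ACO5 replicate 2 or exposed replicate 4, 2 without exposed replicate 1, 3 without ACO3 replicate 1, 6 without ACO5 replicate 5, 8 without ACO3 replicate 2, 9 without ACO4 replicate 3 or 4, 10 without ACO5 replicate 1, 12 without ACO5 replicate 4 and 49 without ACO3 replicate 4. For MECL 500 ppm, 90 genes rose and 343 fell after quantile normalization. The MECL 500 ppm count was 3 without ACO5 replicate 4, 4 without ACO4 replicate 1, 5 without ACO4 replicate 4 and 6 without ACO5 replicate 3. For MECL 2000 ppm, 39 genes rose and 147 fell after quantile normalization and its arrays alone did not call Wfdc3 or Smoc2 (adjusted p = 0.0924 to 0.109). The MECL 2000 ppm count was 1 without ACO3 replicate 2, ACO4 replicate 3 or 4 or exposed replicate 2 or 3 and 7 without ACO5 replicate 3.

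Across the exposed methylene chloride groups, the change fitted from 100 to 4000 ppm was 4.16 ± 0.34 for Dbp (adjusted p = 2.49e-08), -1.39 ± 0.15 for Arntl (adjusted p = 2.37e-06), -1.22 ± 0.12 for Spon2 (adjusted p = 2.21e-07) and -1.17 ± 0.15 for Eln (adjusted p = 2.19e-05). It was 1.28 ± 0.39 for the secretoglobin gene Scgb3a1, a top gene of control axis 2 (adjusted p = 0.0114). Scgb3a1 was not called with any air set at 0 ppm (adjusted p = 0.0796 to 0.102). In all, 3672 genes rose and 2036 fell with concentration. The number called was 3187 fitted on log10 concentration, 1891 with ACO3 added at 0 ppm, 549 with ACO4 and 1391 with ACO5.

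**Figure D3:**
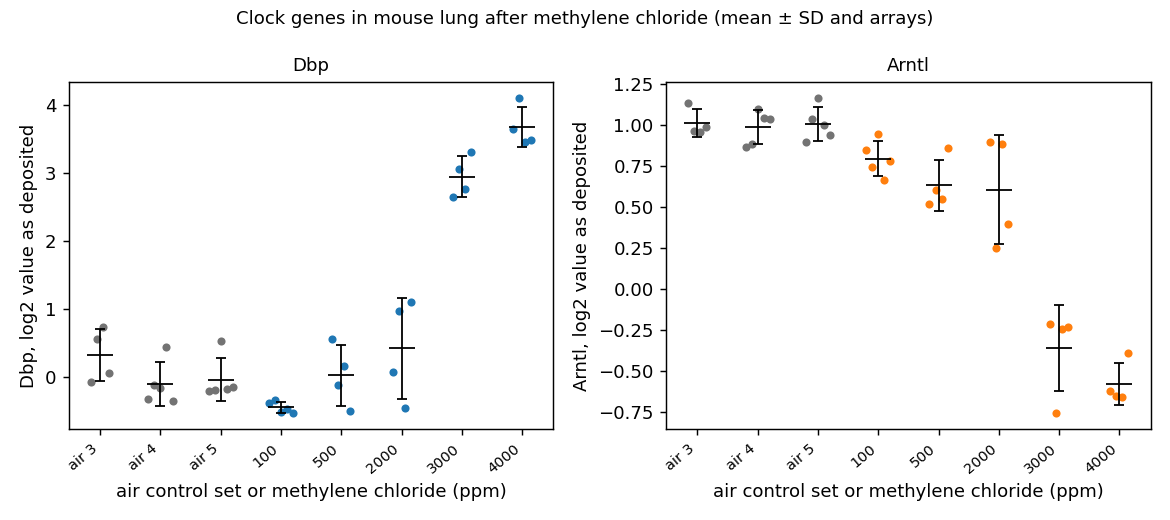
Log2 values as deposited of Dbp and Arntl by methylene chloride concentration in ppm and in the air control sets, by array (points) with the group mean and SD (bars). Mean Dbp was -0.44, 0.43, 2.95 and 3.68 at 100, 2000, 3000 and 4000 ppm and -0.10 to 0.33 in the control sets.

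Propylene glycol mono-t-butyl ether (PGBE, 1200 ppm inhaled, n = 4) raised the clock gene Per2 1.74-fold (0.80 ± 0.10, adjusted p = 9.33e-05), which held with each array left out. In these mice 4 of 18 clock genes rose and 0 fell (9 and 1 adjusted over the list alone, median 0.37, camera adjusted p = 0.0092, or 0.495 estimated), not called with its arrays alone (adjusted p = 0.0825). Also, 0 of 9 adipose tissue genes rose and 1 fell (0 and 6 adjusted over the list alone, median -0.77, camera adjusted p = 7.5e-09, or 0.423 estimated). Without ACO3 replicate 4 the median was -0.57 (camera adjusted p = 5.89e-07). The 1 that fell, the lipid droplet gene Cidea (-0.88 ± 0.16), lost its call without ACO3 replicate 4 (-0.65, adjusted p = 0.696). In all, 83 genes rose and 8 fell. For PGBE, 14 genes rose and 4 fell after quantile normalization and its arrays alone gave 31 calls, without Cidea (adjusted p = 0.298). The PGBE count was 16 without ACO3 replicate 4, 22 without PGBE replicate 1, 27 without PGBE replicate 3, 28 without ACO3 replicate 3, 58 without ACO4 replicate 2 or ACO5 replicate 1 and 59 without ACO5 replicate 5. Ethylene oxide (ETOX, 100 ppm inhaled, n = 4) gave 0 calls by limma, with 68 genes at an unadjusted p under 0.05 and 0 calls after quantile normalization or with any 1 array left out.

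The 26 chemicals were also compared by whether lung tumours were reported in female mice in long-term bioassays, a class taken from general knowledge of those studies and not from the labels, with array batch as a covariate. NRF2 and glutathione genes had a mean log2 fold change of 0.23 ± 0.28 (SD, n = 13) over chemicals with tumours and 0.09 ± 0.14 (n = 13) over those without (permutation p = 0.132, adjusted p = 0.546). Erythroid and blood genes had the lowest permutation p of the 30 lists, 0.0403, with a difference of -0.23 within batches (adjusted p = 0.522). Of 13524 genes limma called 0, with 1212 at an unadjusted p under 0.05 and a smallest adjusted p of 0.509.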

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

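The tests of explanations for the counts of BBMP, TCPN, IODO and MACR and for the clock genes, and the counts over other splits of the arrays, were set up only after the results were seen.

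The counts of BBMP and TCPN, 1465 and 1267, may reflect a wider spread of values over each array, since 1.64% and 8.37% of the called genes were called in the same direction after quantile normalization within the batch. Among the genes that rose, the median log2 fold change went from 0.34 (SD 0.12, median SE 0.10) to 0.17 (SD 0.10, median SE 0.08) in BBMP and from 0.48 (SD 0.20, median SE 0.12) to 0.32 (SD 0.18, median SE 0.11) in TCPN, so calls ended because changes shrank more than their errors. A single array also bears on both, with 8 calls without BBMP replicate 3 and 132 without CCO6 replicate 4. Of their squared changes 65.3% and 67.4% lay along the first 2 axes of variation within control sets, and 8.12% and 0.980% of 10000 draws of control arrays, each minus its set's mean, shifted as far along them. Such variation between arrays cannot be told apart, since the share of splits with as many calls, 1 of 35 and 1 of 100, excludes chance only without a correction over the 34 groups, and a change of many transcripts by the chemicals themselves stays open, untested.

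The counts of IODO and MACR, 3708 and 708, came with 77.8% and 82.4% of the squared changes along these axes, and the groups were picked for that share. Array-to-array variation cannot be told apart, since 1.38% and 1.45% of the draws shifted as far, between the 5% and the 0.147% (5% over 34 groups) that would settle it, and 7 and 2 of 35 splits gave as many calls. RNA degradation cannot be told apart, since the beta-actin 3' minus 5' difference was -0.344 in IODO (exact permutation p = 0.0286) and 0.0781 in MACR (exact permutation p = 0.229), past the test in 1 group alone, while TFEL, at -0.381, had 3.24% of its squared changes along the axes. An effect of the chemicals on the same genes stays open, untested.

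At 4000 ppm methylene chloride Dbp was 3.35 ± 0.42 against ACO3, 3.78 ± 0.40 against ACO4 and 3.72 ± 0.40 against ACO5. A call needs a rise against each set, so no set was tested as the source. For clock genes of every group, time of day cannot be told apart from exposure, as the labels hold no collection time. Over 58 control arrays, each value minus its set's mean, Dbp and Arntl had Pearson's r -0.591 (permutation p = 1e-05, the smallest they can give) and Spearman's rho -0.484 (permutation p = 0.00016), the only relation computed, and r was -0.497 without the 2 arrays farthest from the median Dbp. Within batches r was -0.823 over 6 arrays, -0.696 over 16 (MALA batch) and -0.632 over 12 (TCFM and IODO batch). The relation did not hold over 24 (MECL batch, r -2.25e-05).

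Of 340 sets of 4 or 5 arrays tested for the named genes, 22 (6.47%) held an array far from the others by Dixon's test, and chance gives about 1 in 20. Log2 values are given with the range of the other arrays. In CCO2, Ces1g at -0.25 in replicate 3 (-0.43 to -0.42) stood apart. In CCO5, Gsto1 at 2.98 in replicate 1 (3.60 to 3.79) stood apart. In ACO4, Mmp12 at 0.0885 in replicate 1 (-0.78 to -0.56), Pon1 at 4.68 in replicate 4 (3.26 to 3.67) and Cldn10 at 2.57 in replicate 4 (1.61 to 1.88) stood apart. Also in ACO4, Scd1 at 4.86 in replicate 2 (5.20 to 5.27), Hnrnpab at 4.04 in replicate 4 (3.81 to 3.87) and Wfdc3 at -0.35 in replicate 4 (-0.63 to -0.58) stood apart. In ACO5, Mmp12 at 0.0122 in replicate 1 (-0.86 to -0.65), Lcn2 at 2.23 in replicate 5 (2.42 to 2.50) and Slc26a4 at -0.0383 in replicate 1 (-0.50 to -0.38) stood apart. Also in ACO5, Gabrp at 2.34 in replicate 3 (1.66 to 1.81), Hnrnpab at 2.99 in replicate 3 (3.83 to 4.17) and Dbp at 0.53 in replicate 3 (-0.20 to -0.14) stood apart. Also in ACO5, Wfdc3 at -0.47 in replicate 2 (-0.56 to -0.54) stood apart. In ACO3, Lcn2 at 1.78 in replicate 4 (2.56 to 2.68) and Arntl at 1.14 in replicate 1 (0.96 to 0.99) stood apart. In TCPN, Saa1 at 3.47 in replicate 2 (-1.22 to -0.67) stood apart. In NPTH 3 ppm, Agr2 at -0.29 in replicate 1 (0.59 to 0.72) stood apart. In MECL 4000 ppm, Arntl at -0.39 in replicate 4 (-0.66 to -0.62) stood apart. In MECL 3000 ppm, Arntl at -0.75 in replicate 2 (-0.24 to -0.21) stood apart. In PGBE, Cidea at -0.38 in replicate 1 (-0.96 to -0.88) stood apart. Outside the gene table, 29 of 64 control probe sets of the array and 2184 of 4173 probe sets without a single gene symbol were called in at least 1 contrast.

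The arrays of each comparison were split in other ways into groups of the same sizes, at most 100 times. This tests no shift shared within a group. The real count is given with the highest of the other splits. Chance was excluded, at a share of splits under 0.05 with no correction over the comparisons, for BBMP (1465 and 7), DCBZ (193 and 81), MALA (231 and 106), MECL 100 ppm (20 and 15), NPTH 0.5 ppm (50 and 4), NPTH 20 ppm (286 and 32), NPTH 30 ppm (277 and 58), TCPN (1267 and 731) and TFEL (964 and 384). So it was for VANP (586 and 65), MALA-DIAZ (132 and 73), MECL trend (5708 and 3748) and NPTH trend (5519 and 1427). For BENZ (4 and 847), MECL 3000 ppm (78 and 116), MECL 4000 ppm (68 and 116), NPTH 10 ppm (75 and 267), NPTH 3 ppm (48 and 132) and PGBE (91 and 95) the share was under 0.05 too, though another split called more genes. For MECL 100 ppm 77.1% of the squared changes lay along the control axes, 0.810% of draws shifted as far and the count was 0 without exposed replicate 2 or 5. Array-to-array variation stays open there and for the MECL trend. Chance was not excluded for ABDQ (124 and 768, 4 of 35), COUM (769 and 5770, 7 of 100), DBET (361 and 1282, 5 of 100), IODO (3708 and 6871, 7 of 35), MACR (708 and 3366, 2 of 35), MECL 2000 ppm (2 and 24, 8 of 100), NAAC (2 and 2, 2 of 35), TCFM (66 and 3240, 6 of 35), TDPP (1 and 2884, 12 of 35), TFEA (13 and 2356, 14 of 35), CCO2-CCO3 (4 and 5444, 10 of 35) and IODO-TCFM (252 and 5205, 7 of 35), with the number of splits that gave as many. With a real count of 0, all 35 or 100 splits gave as many, with highest others of 1 for CMPH, 8 for DIAZ, 110 for ETOX, 219 for MECL 500 ppm, 4502 for CCO5-CCO6, 595 for ACO3-ACO4, 39 for ACO3-ACO5, 581 for ACO4-ACO5, 2747 for TFEL-TFEA and 0 for lung tumour class. The 10 splits were too few for a share under 0.05 in BFUR (251 and 50), NAPD (148 and 5), NEDD (12 and 1), PCNB (1 and 2) and NAPD-NEDD (208 and 4). Other splits gave several-fold the real count for ABDQ, BENZ, COUM, DBET, MACR, MECL 2000 ppm, NPTH 10 ppm, TCFM, TDPP, TFEA, CCO2-CCO3 and IODO-TCFM. The source of this sample structure, perhaps single arrays, was not tested.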

How the results depend on the processing

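The alternatives that left out arrays of control comparisons, pairs, trends and lists, or arrays of low RNA integrity, were chosen after seeing the data. No paired analysis was possible because the labels give animal numbers but no replicate number shared between groups. Over the named genes, direction and call stayed in 164 of 166 tests after quantile normalization, 164 of 166 without the filter, 152 of 166 with the mean of all probe sets, 109 of 154 with the arrays of the contrast alone and 2019 of 2141 with 1 array left out. Genes were preferred for the last of these, so that share says nothing about stability. Both stayed in 230 of 230 tests against each control set alone, as the rule for a call requires, 87 of 87 against the mean of the sets, 29 of 36 trend tests with a control set at 0 ppm and 67 of 67 without the 2 control arrays of low RNA integrity, while 32 arrays have no such number. The 1 reversal among these was Saa1 in TCPN, at -0.0838 without TCPN replicate 2. The named lists kept direction and call in 49 of 50, 49 of 50, 49 of 50 and 48 of 50 tests under the first 4 of these settings, in 589 of 596 with 1 array left out and in 12 of 50 with an estimated correlation, which left 8 of the 1020 tests of exposure contrasts called. The values are log2 signals over each array's mean, and without the detection calls of the array files the background cannot be set apart from low signal.

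The number of called genes changed by over 1.5 times in these cases, and the cause was not tested unless stated. After quantile normalization it was 842 for ABDQ, 30 for BBMP, 1 for CMPH, 1550 for COUM, 441 for DCBZ, 3418 for MACR, 695 for MALA, 760 for MECL 100 ppm, 186 for MECL 2000 ppm, 304 for MECL 3000 ppm, 103 for MECL 4000 ppm, 433 for MECL 500 ppm, 1 for NAAC, 237 for NAPD, 2 for NEDD, 92 for NPTH 0.5 ppm, 148 for NPTH 10 ppm, 472 for NPTH 20 ppm, 91 for NPTH 3 ppm, 504 for NPTH 30 ppm, 18 for PGBE, 1540 for TCFM, 206 for TCPN, 623 for TFEA, 1648 for TFEL, 953 for VANP, 69 for CCO2-CCO3, 7 for CCO5-CCO6, 2 for ACO3-ACO4, 2 for ACO4-ACO5, 318 for NAPD-NEDD and 110 for IODO-TCFM. Without the low value filter, which adds genes to the correction, it was 79 for ABDQ, 1511 for COUM, 1 for DIAZ, 338 for MACR, 9 for MECL 100 ppm, 6 for NEDD, 35 for TCFM and 4439 for TCPN. With the mean of all probe sets it was 237 for DBET, 1 for DIAZ, 7 for MECL 500 ppm, 1 for NAAC, 1 for NEDD, 29 for NPTH 0.5 ppm, 190 for PGBE, 39 for TCFM and 1 for CCO5-CCO6. With the arrays of the contrast alone, which leaves fewer arrays to estimate the spread, it was 2 for ABDQ, 0 for BENZ, 1 for BFUR, 17 for COUM, 25 for DBET, 5 for DCBZ, 0 for IODO, 0 for MACR, 355 for MALA, 146 for MECL 100 ppm, 39 for MECL 3000 ppm, 1911 for NAAC, 1 for NEDD, 17 for NPTH 0.5 ppm, 31 for PGBE, 137 for TCFM, 14 for TCPN, 0 for TDPP, 0 for TFEA, 0 for CCO2-CCO3, 542 for NAPD-NEDD, 0 for IODO-TCFM and 1 for MALA-DIAZ. Against the mean of the control sets, a single and less strict test, it was 19 for BENZ, 2453 for COUM, 1519 for DBET, 693 for DCBZ, 3056 for MECL 100 ppm, 899 for MECL 2000 ppm, 708 for MECL 3000 ppm, 249 for MECL 4000 ppm, 1977 for MECL 500 ppm, 292 for NPTH 0.5 ppm, 410 for NPTH 10 ppm, 1323 for NPTH 20 ppm, 219 for NPTH 3 ppm, 1044 for NPTH 30 ppm, 1741 for PGBE, 3182 for TCPN and 1563 for VANP. Set against CCO3 alone, it was 112 for BENZ, 1451 for COUM and 640 for DBET. Set against CCO2 alone, it was 1574 for COUM and 1000 for DBET. Set against CCO5 alone, it was 530 for DCBZ and 2429 for TCPN. Set against ACO3 alone, it was 57 for MECL 100 ppm, 35 for MECL 2000 ppm, 189 for MECL 3000 ppm, 123 for MECL 4000 ppm, 60 for MECL 500 ppm, 151 for NPTH 0.5 ppm, 228 for NPTH 10 ppm, 679 for NPTH 20 ppm, 121 for NPTH 3 ppm, 663 for NPTH 30 ppm and 945 for VANP. Set against ACO4 alone, it was 1723 for MECL 100 ppm, 290 for MECL 2000 ppm, 399 for MECL 3000 ppm, 104 for MECL 4000 ppm, 992 for MECL 500 ppm, 113 for NPTH 0.5 ppm, 313 for NPTH 10 ppm, 641 for NPTH 20 ppm, 109 for NPTH 3 ppm, 818 for NPTH 30 ppm, 721 for PGBE and 1143 for VANP. Set against ACO5 alone, it was 375 for MECL 100 ppm, 24 for MECL 2000 ppm, 234 for MECL 3000 ppm, 173 for MECL 4000 ppm, 2 for MECL 500 ppm, 166 for NPTH 0.5 ppm, 122 for NPTH 10 ppm, 527 for NPTH 20 ppm, 90 for NPTH 3 ppm, 692 for PGBE and 905 for VANP. The MECL trend called 3187 on log10 concentration and 1891, 549 and 1391 with ACO3, ACO4 and ACO5 at 0 ppm. Without arrays of an RNA integrity number under 7 it was 6 for MECL 100 ppm, 10 for MECL 500 ppm, 154 for PGBE, 2 for CCO5-CCO6 and 1 for ACO3-ACO4. With 1 array left out it ranged over 132 to 1999 for TCPN, 18 to 1008 for BFUR, 12 to 460 for ABDQ, 0 to 1 for CMPH, 8 to 3084 for BBMP, 0 to 11 for TDPP, 1 to 4 for BENZ, 1 to 4 for NAAC, 0 to 2695 for MACR, 2 to 5364 for IODO, 4 to 1250 for TCFM, 0 to 49 for MECL 100 ppm, 1 to 7 for MECL 2000 ppm, 38 to 86 for MECL 3000 ppm, 42 to 71 for MECL 4000 ppm, 0 to 6 for MECL 500 ppm, 21 to 69 for NPTH 0.5 ppm, 38 to 76 for NPTH 10 ppm and 158 to 290 for NPTH 20 ppm. It also ranged over 28 to 59 for NPTH 3 ppm, 16 to 121 for PGBE, 0 to 2 for ACO3-ACO5, 0 to 2 for DIAZ, 55 to 257 for MALA, 0 to 825 for TFEA, 307 to 1003 for TFEL, 4 to 2120 for IODO-TCFM, 1 to 2 for PCNB, 0 to 2 for ACO3-ACO4, 150 to 540 for DBET, 114 to 188 for DCBZ, 0 to 2 for CCO5-CCO6, 145 to 1749 for COUM, 0 to 22 for CCO2-CCO3, 20 to 202 for MALA-DIAZ, 0 to 258 for TFEL-TFEA, 1 to 41 for NEDD and 135 to 199 for NAPD-NEDD. For ETOX, NPTH 30 ppm, VANP, ACO4-ACO5, NPTH trend, MECL trend, NAPD and lung tumour class no array or chemical left out changed it that far.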

Other observations

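Calls were counted over the 26 chemicals, each at its highest concentration, and the genes named here were chosen after these counts were seen. Ces1g was called higher in 10 chemicals, Nqo1 and Sptssb, for a subunit of serine palmitoyltransferase, in 9 each, and Gpx2, Cbr3 and Aoc1 in 8 each. Gsto1 and Cxcl17 were called higher in 7 each and Cyp1a1 in 6, and none of these 9 genes was called lower in any. Every exposed array lay on the side of the call, apart from 3 of 4 for Cyp1a1 in IODO and for Aoc1, Cbr3, Gpx2 and Sptssb in MALA. In all, 7426 genes were called in at least 1 chemical and 31 in 6 or more, against 0.411 on average and at most 4 with the calls of each chemical placed at random over 1000 draws. That comparison takes genes as equally likely to be called and leaves out that some chemicals share control sets.

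Across genes, which are not independent replicates, BBMP replicates 2 and 3 had a higher r with MALA replicates 2 and 3 (0.996 and 0.994) than with any array of their own group, by 1.39e-05 and 0.000469, the first being the highest r between groups. Of 133 exposed arrays 64 were closest to an array of another group. A wrong label was not tested.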
